A study of Homo sapiens with 24 samples.

How the data were processed

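RNA was measured by ribodepleted, strand-specific RNA sequencing in 24 libraries of human pluripotent and trophoblast cells. They form 12 groups of 2 libraries: a control short hairpin RNA (shCon) or one against the histone variant gene H2AJ (shH2AJ), each in 6 models. ESC-Naive and ESC-Primed are H1 embryonic stem cells in the naive and the primed state, TSC-Naive and TSC-Primed are trophoblast stem cells whose labels give the same H1 sources, STB-Primed is syncytiotrophoblast whose label gives the primed H1 source, and Okae is a separate trophoblast stem cell line. Ribosomal RNA was depleted from total RNA with Ribo-Zero and libraries were made with a NEBNext Ultra Directional kit.

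The authors deposited 1 table of raw counts of reads per Ensembl gene, made with STAR, SAMtools, Subread and featureCounts against hg38. Versions, the gene annotation, the strand setting of the counting and the treatment of reads that map to several places are not stated. The table holds 28191 genes, of which 27912 have a symbol. Coordinates came from GENCODE release 29, which held 28085 of the identifiers and may not be the annotation the authors used. The 48 genes XIST, TSIX and those on chromosome Y were left out of all tests and tables. The 8 columns of the naive models were matched to samples by name. The 12 columns marked H1 do not name the primed state and were matched to the primed models because the naive models, also from H1, had columns of their own. The 4 columns marked CT were matched to Okae because no other samples remained. The table was found to list a gene in a model only when the highest of its 4 libraries had at least 21 counts, and to hold 0 in all 4 otherwise. Those zeros are not measured zeros, so a gene was tested only where every model of the comparison listed it. The joint fits and the voom values were nevertheless computed on all 24 libraries with the zeros of other models in place. Those zeros could therefore enter the estimate of a gene's spread. The numbers of genes listed were 17762 in ESC-Naive, 18582 in ESC-Primed, 18285 in TSC-Naive, 22261 in TSC-Primed, 22171 in Okae and 21473 in STB-Primed, with 13697 in all 6 models.

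Library totals ran from 22.51 to 86.43 M (mega) counts, with a median of 38.26 M. At that depth a level of 1 in counts-per-million (CPM) stood for at least 22.51 counts in every library. Floors and intervals of counts cover counting error only, because reads without molecular identifiers are not independent molecules. A group at 0 counts in both libraries was given no fold change.

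Counts were analysed in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by TMM, genes were kept by filterByExpr on the 12 groups (27246 genes), and a quasi-likelihood model with robust dispersion and 1 mean per group was fitted to all 24 libraries together. Contrasts were two-sided quasi-likelihood F tests, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. Standard errors (SE) of the log2 fold change are approximate: each is its absolute value over the square root of the F statistic. At low counts they may not describe the uncertainty of the fold. Levels are CPM with the SD over the 2 libraries of a group. The comparisons were knockdown against control in each model, its average over the 6 models and over the 3 trophoblast stem cell models, 5 differences of the knockdown effect between models, and 5 comparisons between control groups. The labels do not say what a replicate number stands for, nor whether the 2 libraries of a group came from separate cultures or infections, so the numbers were not used to pair samples. Every p therefore measures the spread between libraries and nothing beyond it.

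Before the data were examined, 34 gene lists were fixed from general knowledge, along with the comparisons, the tests and the rule for naming genes. Each list with at least 5 measured members was tested with camera in limma 3.58.1 on voom values of all libraries, with a preset correlation between genes of 0.01, and adjusted over all lists and the 6 knockdown comparisons together. An estimated correlation was the alternative. Members that passed adjusted p below 0.05 over all genes are counted as risen or fallen, and those adjusted over the list alone are given beside them.

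The named genes of each knockdown comparison are H2AJ and the 6 genes in each direction with the largest absolute log2 fold change among those called. They also needed a mean of at least 1 CPM in the 4 libraries, both knockdown libraries beyond both control libraries, and an established symbol. For each list past its threshold the 3 members with the smallest p were named. Averages and differences name 5 genes in each direction. Comparisons of controls name the 3 members with the largest change from each of the cell identity lists, and the variant histones of the H2A family.

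Alternatives chosen along with these were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, an added minimum absolute log2 fold change of 1, a fit to the compared groups alone, the replicate number as a block within each model, camera with an estimated correlation, fry, and leaving out each library in turn. With 1 library left out, the lone library of its group was assumed to vary like the other groups. Added after the data were seen were voomLmFit with weights per model, unlisted genes taken as zeros, distal chromosome 13 left out, the naive models left out, and camera on the edgeR statistics. The tests were also tested on simulated data with the spread of each model and 200 changed genes per knockdown comparison. The spread differed between models, with a coefficient of variation fitted alone of 0.042 in ESC-Primed, 0.067 in TSC-Primed, 0.177 in Okae, 0.199 in STB-Primed, 0.229 in ESC-Naive and 0.468 in TSC-Naive, against 0.227 over all libraries. On simulated data the joint fit recovered 31% to 54% of 2-fold and 78% to 88% of 4-fold changes. Fitted alone, the libraries of ESC-Primed gave 92% of 2-fold changes with 12 of 230 calls unchanged genes and those of TSC-Primed 87% with 7 of 220, against 32% in both for the joint fit. In TSC-Naive, however, 2331 of the 2480 simulated calls of the joint fit were unchanged genes. So were 34 of 152 in ESC-Naive, 125 of 312 for the average over 3 trophoblast stem cell models and 34 of 248 for that over 6. With no difference between models simulated, the joint fit called 489 genes for TSC-Naive against ESC-Naive and 190 for TSC-Naive against TSC-Primed, and 0 for each of the other 3 differences. For the first 2 of these the DESeq2 Wald test called 1367 and 974 genes and voomLmFit 0 and 0, and for trophoblast against embryonic stem cell models, which also holds TSC-Naive, the Wald test called 48. The simulated libraries were drawn independently, with no likeness by replicate number. The real TSC-Naive libraries correlated more with those of the same number (r 0.971 and 0.972) than within a group (0.933 and 0.932). Simulated counts that hold TSC-Naive therefore need not give the false calls of the real libraries, for which the joint fit called 179 genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and tables were prepared with pandas 2.3.3 and numpy 2.4.6.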

Results

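Gene expression was measured by ribodepleted RNA sequencing in 24 libraries from 6 cell models, each with 2 libraries of a control hairpin (shCon) and 2 of a hairpin against H2AJ (shH2AJ). H2AJ encodes the histone H2A variant H2A.J, and the series asks what its depletion does to pluripotent stem cells and to the trophoblast lineage, which forms the placenta. The models were naive and primed H1 embryonic stem cells (ESC-Naive, ESC-Primed), trophoblast stem cells from the same H1 sources (TSC-Naive, TSC-Primed), the Okae trophoblast stem cell line and syncytiotrophoblast (STB-Primed). Syncytiotrophoblast is the fused, hormone-secreting outer layer of the placenta. Total counts per library, in units of M (mega), were 25.24 and 29.76 for ESC-Naive controls and 26.65 and 31.34 for their shH2AJ libraries. ESC-Primed had 34.62 and 37.34 against 44.07 and 46.9, and TSC-Naive 31.27 and 32.47 against 29.53 and 34.19. TSC-Primed had 32.27 and 42.59 against 22.51 and 39.17, Okae 72.16 and 86.43 against 69.62 and 80.83, and STB-Primed 49.08 and 57.59 against 57.48 and 62.97. All values below are from edgeR with n = 2 libraries per group unless another test is named, and all positions are in hg38.

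The first question was whether H2AJ was lowered. H2AJ (ENSG00000246705, chromosome 12, 14774383 to 14778002) fell in 4 of the 6 models and was not detectably lower in both naive models. In ESC-Primed it went from 57 ± 0.57 to 11.9 ± 0.67 CPM (mean ± SD, n = 2), a fold of 4.79 and a log2 fold change of -2.26 (SE 0.24, adjusted p 0.001). TSC-Primed went from 47.2 ± 4.5 to 6.64 ± 0.42 (log2 -2.83, SE 0.25, adjusted p 1.4e-05), and Okae from 87.2 ± 1.3 to 9.01 ± 1.8 (log2 -3.27, SE 0.25, adjusted p 5.1e-06). STB-Primed went from 98.8 ± 39 to 19.2 ± 2.4 (log2 -2.36, SE 0.24, adjusted p 1.4e-05). ESC-Naive controls held only 7.56 ± 1 and TSC-Naive controls 9.94 ± 2.7 CPM, close to the level of H2AJ left after knockdown elsewhere. Libraries labelled shH2AJ held 6.2 ± 0.84 in ESC-Naive (log2 -0.29, SE 0.24, adjusted p 1) and 10.9 ± 0.12 in TSC-Naive (log2 0.14, SE 0.23, adjusted p 0.89). The knockdown differed between TSC-Naive and TSC-Primed (difference 2.97, SE 0.33, adjusted p 3.1e-04). It was not shown to differ between STB-Primed and TSC-Primed (0.47, SE 0.32, adjusted p 0.4), TSC-Primed and ESC-Primed (-0.57, SE 0.32, adjusted p 0.55), TSC-Naive and ESC-Naive (0.42, SE 0.33, adjusted p 0.89) or trophoblast and embryonic stem cell models (-0.81, SE 0.2, adjusted p 0.084). Each p was adjusted over all genes of its comparison, 13697 for the last, which also averaged in both naive models. Values that did not pass do not show equal knockdown. In ESC-Primed the fold stayed between -2.31 and -2.20 with any 1 library left out, but the call was lost without shH2AJ replicate 1 (-2.20) or replicate 2 (-2.31).

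**Figure D1:**
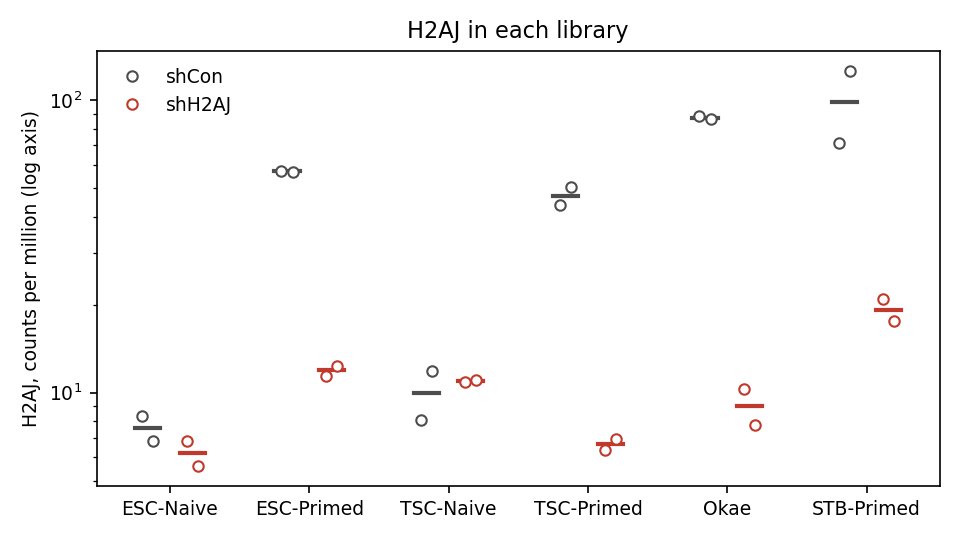
H2AJ in CPM on a log axis, 1 circle per library and a bar at the mean of the 2 libraries of each group, by model. In the 2 naive models the control mean was 7.56 and 9.94, and in the other models it was 47.2 or higher and the shH2AJ mean 19.2 or lower.

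In STB-Primed, the model labelled syncytiotrophoblast, most genes of the syncytiotrophoblast list rose. The placental lactogen genes CSH2 (ENSG00000213218, chromosome 17, 63872012 to 63873766) and CSH1 (ENSG00000136488, chromosome 17, 63894909 to 63896661) rose with log2 fold changes of 5.50 (SE 0.53, adjusted p 0.0015) and 4.56 (SE 0.39, adjusted p 0.001). CSH1 went from 0.56 and 0.47 to 12.36 and 12.29 CPM, and CSH2 from 0.16 and 0.37 to 11.44 and 12.22. By DESeq2 the calls of CSH1, CSH2, MUCL1 and PSG3 were lost, and 8 of the 12 named genes besides H2AJ passed. Placental growth hormone GH2 (log2 5.83, SE 0.72), the pregnancy-specific glycoprotein PSG3 (4.85, SE 1.21), PAGE4 (4.95, SE 0.65) and MUCL1 (5.54, SE 0.61) also rose. The control levels of GH2 and MUCL1 were at most 0.08 CPM, so the size of their rise is poorly fixed. Of the 49 measured members of the syncytiotrophoblast list, 41 rose and 1 fell (42 and 1 adjusted over the list alone), with a median of 3.28 (camera adjusted p 2.1e-28, adjusted p = 0.21 with an estimated correlation). They included HSD11B2, which inactivates cortisol (3.62, SE 0.40, adjusted p 3.0e-05), and the lipid transporter MFSD2A, which also serves as the receptor of syncytin-2 (2.40, SE 0.27, adjusted p 5.9e-05). The exception was the protease inhibitor TFPI2, which fell (-1.08, SE 0.13, adjusted p 5.9e-05). Lists of fibroblast and stromal genes (median -0.66, 1 of 14 lower, camera adjusted p 0.2) and of BMP and TGF-beta targets (median -0.77, 3 of 13 lower, camera adjusted p 0.059) had medians below 0 in the same libraries without passing.

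Other groups moved in the same libraries. In the cell fusion and steroid hormone list 8 of 15 members rose and 2 fell (9 and 3 adjusted over the list alone; median 1.51, camera adjusted p 3.8e-04, adjusted p = 0.33 with an estimated correlation). The estrogen-forming enzyme HSD17B1 (2.52, SE 0.27) and ferredoxin FDX1, which passes electrons to steroid-making enzymes (1.76, SE 0.12), were among those that rose. Of 33 interferon-stimulated genes 15 rose and none fell (16 and 0 adjusted over the list alone; median 1.56, camera adjusted p 2.7e-07, adjusted p = 0.80 with an estimated correlation). IFI6 was at 2.28 (SE 0.29), the RNA sensor OAS3 at 2.61 (SE 0.36) and DDX60 at 1.78 (SE 0.30). In the trophoblast stem cell list 8 of 26 members rose and 0 fell (9 and 0 adjusted over the list alone; median 0.33, camera adjusted p 0.0016, adjusted p = 0.80 with an estimated correlation), among them PEG10 (1.81, SE 0.23), the growth factor receptor EGFR (2.19, SE 0.36) and PAGE4. All 13 mitochondrially encoded genes were measured and 11 fell (12 adjusted over the list alone; median -0.96, camera adjusted p 7.8e-04, adjusted p = 0.80 with an estimated correlation), with the cytochrome oxidase genes MT-CO2 at -1.17 (SE 0.22), MT-CO1 at -1.09 (SE 0.22) and MT-CO3 at -0.91 (SE 0.22). Their share of all counts was 0.93% and 0.85% in controls and 0.42% and 0.43% after knockdown.

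The extravillous trophoblast list had 6 of 22 members higher and 1 lower, the same numbers adjusted over the list alone (median 0.16, mean 0.63, camera adjusted p 0.022, adjusted p = 0.33 with an estimated correlation). Among them were the invasive trophoblast antigen HLA-G (3.22, SE 0.16), AOC1, which breaks down histamine (3.88, SE 0.27), and the VEGF receptor FLT1 (2.52, SE 0.33). Of 49 replication-dependent histones 19 rose (22 adjusted over the list alone; median 0.50, camera adjusted p 9.7e-06, adjusted p = 0.80 with an estimated correlation). H3C7 was at 0.92 (SE 0.14), HIST1H3C at 1.07 (SE 0.19) and H2AC16 at 1.06 (SE 0.20). Of 16 cholesterol synthesis genes 7 rose and 1 fell, the same adjusted over the list alone (median 0.27, camera adjusted p 0.021, adjusted p = 0.80 with an estimated correlation), including INSIG1 (1.77, SE 0.16), DHCR7 (0.81, SE 0.13) and the receptor LDLR (1.01, SE 0.16). These calls rested on control replicate 1: without it the adjusted p was 0.05 for extravillous genes, 0.2 for histones and 0.19 for cholesterol synthesis, the highest of the 4 values with 1 library left out. In that library FN1 alone took 7.24% of the counts.

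Among the genes that fell in STB-Primed were clustered protocadherins, cell-adhesion genes that give neurons their surface identity. All 53 measured protocadherins of the chromosome 5 clusters, a set chosen after its values were seen, were below 0 and 30 of them fell (median -1.58, Fisher's exact test, two-sided, p 6.5e-18). PCDHB5 (ENSG00000113209, chromosome 5, 141135218 to 141138625) fell from 28.93 and 40.92 to 3.09 and 3.38 CPM (log2 -3.43, SE 0.24, adjusted p 5.1e-06), and PCDHB15 (-3.75, SE 0.69) and PCDHGA9 (-3.65, SE 0.79) fell as well. PITX2, a homeobox transcription factor (ENSG00000164093, chromosome 4, 110617423 to 110642123), fell from 13.13 and 12.73 to 1.26 and 1.15 (log2 -3.42, SE 0.30, adjusted p 3.8e-06). CCDC85A (-3.48, SE 0.56) and the sialyltransferase ST6GAL2 (-3.44, SE 0.53) fell too. In all, 2235 genes rose and 1969 fell among 21207 tested. The total of 4204 became 2328 without control replicate 1, 2343 without shH2AJ replicate 1 and 1897 without shH2AJ replicate 2, and 10 of the 12 named genes besides H2AJ passed with any 1 library left out. The paralogs CSH1, CSH2 and GH2, the PSG genes, HLA-G and histones share sequence, protocadherins of the alpha and of the gamma cluster share 3' exons, and the treatment of shared reads is not stated.

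**Figure D2:**
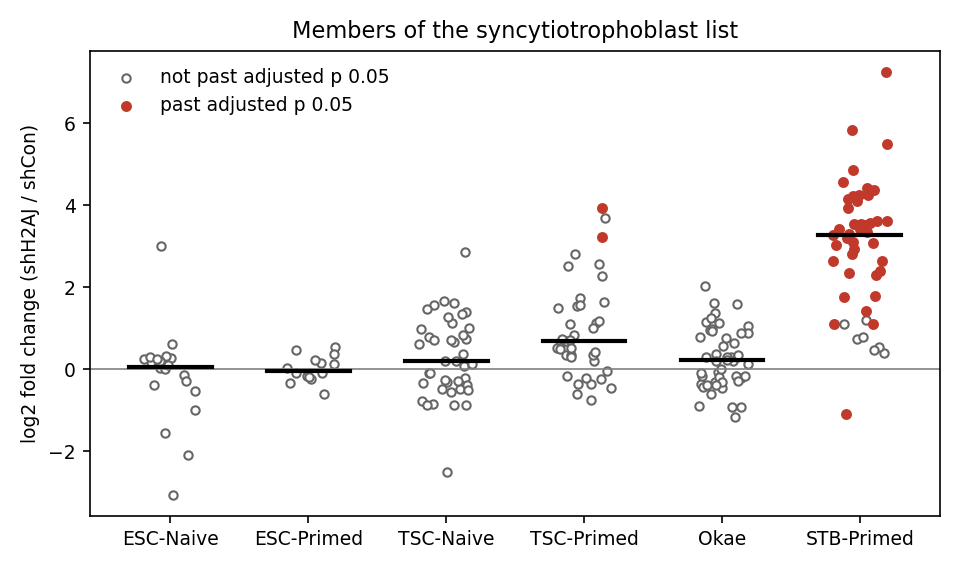
Log2 fold change (shH2AJ over shCon) of each measured member of the syncytiotrophoblast list by model, filled circles for members past adjusted p 0.05 and a bar at the median. STB-Primed has a median of 3.28 with 41 members higher, and 2 members passed in TSC-Primed.

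In TSC-Primed, the trophoblast stem cells from primed H1 cells, the zinc importer SLC39A4 (ENSG00000147804, chromosome 8, 144409742 to 144416895) rose from 1.91 and 1.86 to 29.05 and 28.55 CPM (fold 15.3, log2 3.93, SE 0.24, adjusted p 3.9e-07). The GABA receptor subunit GABRR2 (ENSG00000111886, chromosome 6, 89257208 to 89315299) rose by 4.52 (SE 0.52, adjusted p 6.3e-04), and PADI1, which converts arginine to citrulline in proteins (ENSG00000142623, chromosome 1, 17205126 to 17246005), by 3.64 (SE 0.28, adjusted p 1.4e-05). NSG2 (3.93, SE 0.62), the potassium channel subunit KCNV2 (3.67, SE 0.43) and SLC26A7 (3.24, SE 0.85) also rose. The chemokine CXCL12 (ENSG00000107562, chromosome 10, 44370165 to 44386493) fell from 14.45 and 16.85 to 1.83 and 1.54 CPM (log2 -3.20, SE 0.23, adjusted p 2.2e-05). GAP43, a protein of growing axons (-2.43, SE 0.48), RHBDL1 (-2.29, SE 0.34), FSTL5 (-2.23, SE 0.42) and the procollagen-processing enzyme ADAMTS14 (-2.15, SE 0.36) fell too.

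Proliferation genes rose in TSC-Primed: 21 of 31 rose and none fell (26 and 0 adjusted over the list alone), with a median of 0.79 (camera adjusted p 7.0e-14, adjusted p = 0.21 with an estimated correlation). Examples were the topoisomerase TOP2A (0.99, SE 0.10), the kinetochore motor CENPE (1.28, SE 0.14) and the mitotic activator CDC20 (1.33, SE 0.17). The rise started from a low level, since TSC-Primed controls were below ESC-Primed controls in all 31 (median -2.89). Ribosomal protein genes moved the other way, with 19 of 27 lower and none higher (26 and 0 adjusted over the list alone; median -0.79, camera adjusted p 2.2e-16, adjusted p = 0.80 with an estimated correlation), including RPS19 (-1.16, SE 0.20), RPL23 (-0.97, SE 0.18) and RPS6 (-1.04, SE 0.20). Of 15 cholesterol synthesis genes 5 rose (8 adjusted over the list alone; median 0.35, camera adjusted p 6.4e-04, adjusted p = 0.80 with an estimated correlation). INSIG1 was at 1.05 (SE 0.16), SQLE at 0.61 (SE 0.10) and the rate-limiting HMGCR at 0.80 (SE 0.14). In the syncytiotrophoblast list PSG1 (3.23, SE 0.52) and PSG11 (3.93, SE 0.88) rose, 2 of 39 by both counts, while SLC22A11 was at 2.81 (SE 0.83, adjusted p 0.073); its median was 0.69 (camera adjusted p 0.017, adjusted p = 0.80 with an estimated correlation). Of 25 p53 targets 2 fell by both counts, CCNG1 (-0.83, SE 0.21) and PHLDA3 (-0.73, SE 0.21), while SESN1 was at -0.32 (SE 0.11, adjusted p 0.11). The p53 list had a median of -0.29 (camera adjusted p 0.033, adjusted p = 0.80 with an estimated correlation), and its call was lost without control replicate 2 (adjusted p 0.19) or shH2AJ replicate 1 (0.057). In all, 607 genes rose and 639 fell among 22245 tested. Other fits called more: 8966 genes passed with the 4 libraries fitted alone, 9072 by voomLmFit and 2447 by the DESeq2 Wald test. The total of 1246 became 406 without control replicate 1, 173 without control replicate 2, 274 without shH2AJ replicate 1 and 210 without shH2AJ replicate 2. With any 1 library left out, 7 of the 11 named genes besides H2AJ passed each time.

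In Okae, an independent trophoblast stem cell line, the epidermal protein SBSN (ENSG00000189001, chromosome 19, 35523367 to 35528351) rose from 0.32 and 0.27 to 5.33 and 7.61 CPM (log2 4.47, SE 0.42, adjusted p 0.0024), though not by DESeq2. GABRR2 (3.47, SE 0.49, adjusted p 0.0042) and NSG2 (2.99, SE 0.53) rose here as in TSC-Primed, along with the potassium channel KCNJ6 (3.46, SE 0.61), the cartilage proteoglycan ACAN (3.12, SE 0.43) and the protease TMPRSS4 (2.98, SE 0.67). The guidance receptor ligand SEMA5A (ENSG00000112902, chromosome 5, 9035026 to 9546075) fell from 4.96 and 5.8 to 0.99 and 0.98 (log2 -2.45, SE 0.28, adjusted p 6.0e-04). SUSD3 (-2.26, SE 0.42), the fatty acid carrier FABP7 (-2.26, SE 0.51), the ketone-using enzyme OXCT1 (-2.20, SE 0.38) and MRGPRX1 (-2.19, SE 0.38) fell as well.

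Targets of p53 were lower in Okae, 6 of 25 falling and none rising (10 adjusted over the list alone), with a median of -0.60 (camera adjusted p 4.2e-09, adjusted p = 0.33 with an estimated correlation). They included MDM2, the ubiquitin ligase of p53 (-1.17, SE 0.10, adjusted p 2.0e-05), SESN1 (-1.11, SE 0.11, adjusted p 6.8e-05) and FDXR (-1.36, SE 0.18, adjusted p 0.0011). Of 50 replication-dependent histones 7 fell (46 adjusted over the list alone; median -0.65, camera adjusted p 1.1e-29, adjusted p = 0.68 with an estimated correlation), such as H3C10 (-0.69, SE 0.15), H2AC12 (-0.75, SE 0.17) and H2AC4 (-0.70, SE 0.16). Of 19 inflammatory and senescence-associated secretory genes 3 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.57, camera adjusted p 0.0056, adjusted p = 0.44 with an estimated correlation): the cytokines IL11 (2.20, SE 0.26) and TNF (2.03, SE 0.31) rose and IGFBP3 fell (-1.59, SE 0.39). Ribosomal protein genes had a median of -0.24 with 0 of 27 called by either count (camera adjusted p 1.8e-04, adjusted p = 0.80 with an estimated correlation); RPS19 was at -0.53 (SE 0.19), RPS6 at -0.48 (SE 0.20) and RPL3 at -0.43 (SE 0.18), and the list's call was lost without shH2AJ replicate 2 (adjusted p 0.65). In all, 301 genes rose and 248 fell among 21690 tested, and 1545 passed by the DESeq2 Wald test, 957 by voomLmFit and 532 with the 4 libraries fitted alone (250 of them shared with the joint fit). The total of 549 became 1655 without shH2AJ replicate 1, 82 without control replicate 1, 89 without control replicate 2 and 116 without shH2AJ replicate 2. Of the 11 named genes besides H2AJ, 2 passed whichever library was left out.

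In ESC-Primed few genes passed. USP3, a deubiquitinase of histone H2A (ENSG00000140455, chromosome 15, 63504511 to 63594640), rose from 15.33 and 14.75 to 29.74 and 33.07 CPM (fold 2.09, log2 1.06, SE 0.12, adjusted p 0.0015), and PTCHD4 rose by 2.94 (SE 0.41, adjusted p 0.017). CD70 (1.98, SE 0.31), ERVH48-1 (1.07, SE 0.18), an endogenous retroviral gene that encodes suppressyn, and BNC1 (0.99, SE 0.15) rose too. FGF4, a growth factor of pluripotent cells (ENSG00000075388, chromosome 11, 69771016 to 69775403), fell from 4.2 and 5.06 to 1.68 and 1.76 (log2 -1.43, SE 0.19, adjusted p 0.037). PCDHB5 (-1.71, SE 0.23), ZNF736 (-0.96, SE 0.16), NACC1 (-0.72, SE 0.13) and PCMTD2 (-0.67, SE 0.11) fell as well. In all, 8 genes rose and 6 fell among 18573 tested, where 741 had an unadjusted p below 0.05. The total of 14 became 3 without control replicate 1, 4 without control replicate 2, 1 without shH2AJ replicate 1 and, by edgeR, 0 without shH2AJ replicate 2 (359 at an unadjusted p below 0.05). With the 4 libraries fitted alone 4375 genes passed, voomLmFit called 3220 and the DESeq2 Wald test called 92. None of the 10 named genes besides H2AJ passed with every library left out in turn, and all 10 passed with the 4 libraries fitted alone.

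Several lists shifted by a little in ESC-Primed, with no member past the threshold over all genes. Core pluripotency genes had a median of -0.16 over 17 members (1 lower and 0 higher adjusted over the list alone; camera adjusted p 0.0056, adjusted p = 0.80 with an estimated correlation). GDF3 was at -0.86 (SE 0.16), SOX2 at -0.31 (SE 0.11) and LEFTY2 at 0.91 (SE 0.26). The 25 p53 targets had a median of 0.20 (camera adjusted p 0.0012, adjusted p = 0.80 with an estimated correlation). RRM2B was at 0.35 (SE 0.12), ZMAT3 at 0.43 (SE 0.19) and GADD45A at 0.38 (SE 0.17). The 50 replication-dependent histones had a median of -0.15 (camera adjusted p 2.6e-07, adjusted p = 0.80 with an estimated correlation). HIST1H3C was at -0.57 (SE 0.18), H2BC3 at -0.68 (SE 0.26) and H3C7 at -0.26 (SE 0.14). The calls of 3 more lists were lost with 1 library left out, and each had adjusted p = 0.80 with an estimated correlation. Transcripts linked to the endogenous retrovirus HERVH had a median of -0.38 over 11 members (camera adjusted p 0.023, and 0.091 without shH2AJ replicate 2). SCGB3A2 was at -0.86 (SE 0.33), ESRG at -0.38 (SE 0.18) and LINC00458 at 0.59 (SE 0.26). Cholesterol synthesis had -0.10 over 16 members (0.028, and 0.075 without control replicate 1 or 0.084 without shH2AJ replicate 2). DHCR7 was at -0.22 (SE 0.12), PCSK9 at -0.40 (SE 0.23) and SQLE at -0.14 (SE 0.10). Mitochondrially encoded genes had 0.33 over 13 members (0.022, and 0.19 without control replicate 2 or 0.057 without shH2AJ replicate 2). MT-ND6 was at 0.61 (SE 0.35), MT-ND3 at 0.34 (SE 0.22) and MT-CO3 at 0.33 (SE 0.22). None of these 3 lists had a member past the threshold adjusted over the list alone, nor did the p53 or the histone list.

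In ESC-Naive, where H2AJ was not detectably lowered, 1 region, chosen after its values were seen, held most of the genes that were lower in libraries labelled shH2AJ. On chromosome 13 from 94154193 to the last gene at 114337626, 61 of 63 protein-coding genes were below 0, with a median of -0.95, and they made up 29 of the 45 genes called lower (Fisher's exact test, two-sided, p 2.7e-63). Named genes of this region were POGLUT2, which glucosylates Notch (-1.40, SE 0.15), and the DNA ligase LIG4 (-1.31, SE 0.17). Outside it, the growth factor BMP7 (ENSG00000101144, chromosome 20, 57168748 to 57266629) fell from 4.03 and 3.01 to 1.13 and 0.82 CPM (log2 -1.84, SE 0.18, adjusted p 2.2e-04). The tumour suppressor RB1, on chromosome 13 from 48303726 to 48599436, fell by 1.52 on the log2 scale (SE 0.20, adjusted p 0.0014), and AIG1 (-1.71, SE 0.26) and MATCAP2 (-2.15, SE 0.40) fell. The deubiquitinase OTUB2 (ENSG00000089723, chromosome 14, 94026329 to 94048930) rose from 0.35 and 0.44 to 1.85 and 1.84 (log2 2.23, SE 0.32, adjusted p 0.0025), with KCNS1 (1.87, SE 0.33), HOOK1 (1.21, SE 0.23), FAM13A (0.99, SE 0.16) and the microtubule-severing SPAST (0.51, SE 0.10). In all, 15 genes rose and 45 fell among 17710 tested, and 12 passed without the distal chromosome 13 genes. Of the 11 named genes besides H2AJ, 4 passed whichever library was left out, and none passed with the 4 libraries fitted alone by edgeR (14 genes called).

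Of the ESC-Naive lists that passed, none had a member called by either count. Primed pluripotency had a median of -0.28 over 14 members (camera adjusted p 0.033, adjusted p = 0.42 with an estimated correlation). ZIC3 was at -0.88 (SE 0.25), TCF7L1 at -0.48 (SE 0.19) and ZIC5, which lies in distal chromosome 13, at -2.30 (SE 0.68). Core pluripotency had -0.13 over 18 members (0.033, adjusted p = 0.80 with an estimated correlation). FOXD3 was at -0.59 (SE 0.33), SOX2 at -0.17 (SE 0.11) and GDF3 at -0.21 (SE 0.14). Replication-dependent histones had -0.14 over 50 members (0.022, adjusted p = 0.94 with an estimated correlation). H2AC12 was at -0.30 (SE 0.17), H2AC6 at -0.29 (SE 0.17) and H2AC16 at -0.25 (SE 0.17). The adjusted p of primed pluripotency was 0.19 without control replicate 1, 0.05 without shH2AJ replicate 1 and 0.17 without shH2AJ replicate 2. That of core pluripotency was 0.31 and 0.057 without control replicates 1 and 2 and 0.36 without shH2AJ replicate 2. The histone list turned direction without control replicate 2 or shH2AJ replicate 1, with an adjusted p of 0.72 in both.

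TSC-Naive showed the same region, with H2AJ again not detectably lowered: 58 of 60 protein-coding genes of distal chromosome 13 were below 0 (median -0.94), and they made up 34 of 92 genes called lower (Fisher's exact test, two-sided, p 4.9e-65). Named members of it were MYO16 (-3.14, SE 0.66) and ADPRHL1 (-2.27, SE 0.47). HLA-G (ENSG00000204632, chromosome 6, 29826967 to 29831125) was lower in both shH2AJ libraries, at 0.2 and 0.29 against 2.02 and 2.54 CPM (log2 -3.18, SE 0.22, adjusted p 2.3e-06), as were the cytokine receptor IL21R (-2.39, SE 0.36), DHRS4L2 (-2.27, SE 0.30) and the synaptic vesicle protein SV2A (-2.09, SE 0.34). Genes called higher included the meiotic chromosome gene SYCP3 (ENSG00000139351, chromosome 12, 101728648 to 101739472; 2.71, SE 0.41, adjusted p 0.006) and MAEL, which silences transposons (ENSG00000143194, chromosome 1, 166975582 to 167022214; 2.75, SE 0.48, adjusted p 0.017). UGT8 (2.83, SE 0.56), DDX53 (2.73, SE 0.49), POF1B (2.67, SE 0.44) and APBA2 (2.60, SE 0.55) were higher too. In all, 87 genes were called higher and 92 lower among 18212 tested, and 112 passed without the distal chromosome 13 genes. The total of 179 became 690 without control replicate 1, 313 without shH2AJ replicate 1 and 963 without shH2AJ replicate 2. The replicates varied more here than in any other model: fitted alone by edgeR the 4 libraries gave 0 calls (301 genes at an unadjusted p below 0.05), voomLmFit gave 0 (280 unadjusted) and the DESeq2 Wald test 611. Of the 12 named genes besides H2AJ, 6 passed whichever library was left out.

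In TSC-Naive the hypoxia and glycolysis list had a median of -0.51, with 3 of 18 members called lower (6 adjusted over the list alone; camera adjusted p 3.2e-07, adjusted p = 0.42 with an estimated correlation). These were the mitophagy receptor BNIP3 (-0.87, SE 0.17), the glycolytic regulator PFKFB4 (-0.98, SE 0.19) and PDK1, which holds pyruvate back from the mitochondria (-0.69, SE 0.14). All 3 calls were lost with the 4 libraries fitted alone, by voomLmFit (adjusted p 1 in each) and without control replicate 2 (0.097, 0.087 and 0.064). BNIP3 and PFKFB4 also lost theirs without shH2AJ replicate 1 (0.055 and 0.063), and PDK1 without control replicate 1 (0.057) or shH2AJ replicate 2 (0.059). Cholesterol synthesis genes had a median of -0.34, with 0 of 15 called and 4 lower adjusted over the list alone (camera adjusted p 1.4e-06, adjusted p = 0.80 with an estimated correlation); INSIG1 was at -0.67 (SE 0.16), SQLE at -0.34 (SE 0.10) and DHCR7 at -0.40 (SE 0.12), and the adjusted p was 0.21 without shH2AJ replicate 2 and 0.059 without control replicate 1. The 50 histones had a median of -0.27 with 0 called by either count (camera adjusted p 3.8e-05, adjusted p = 0.80 with an estimated correlation); H2AC13 was at -0.66 (SE 0.17), H2AC14 at -0.55 (SE 0.16) and H3C6 at -0.72 (SE 0.22), and the adjusted p was 0.57 without control replicate 2. The 13 mitochondrially encoded genes had a median of 0.45 with 0 called by either count (camera adjusted p 0.029, adjusted p = 0.80 with an estimated correlation); MT-ATP8 was at 0.83 (SE 0.37), MT-ND1 at 0.65 (SE 0.30) and MT-ND6 at 0.68 (SE 0.34). That list was at 0.33 without control replicate 1 and turned direction without shH2AJ replicate 1 (adjusted p 0.0064), the library in which these genes held 3.62% of the counts against 1.64%, 2.04% and 2.1% in the others.

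**Figure D3:**
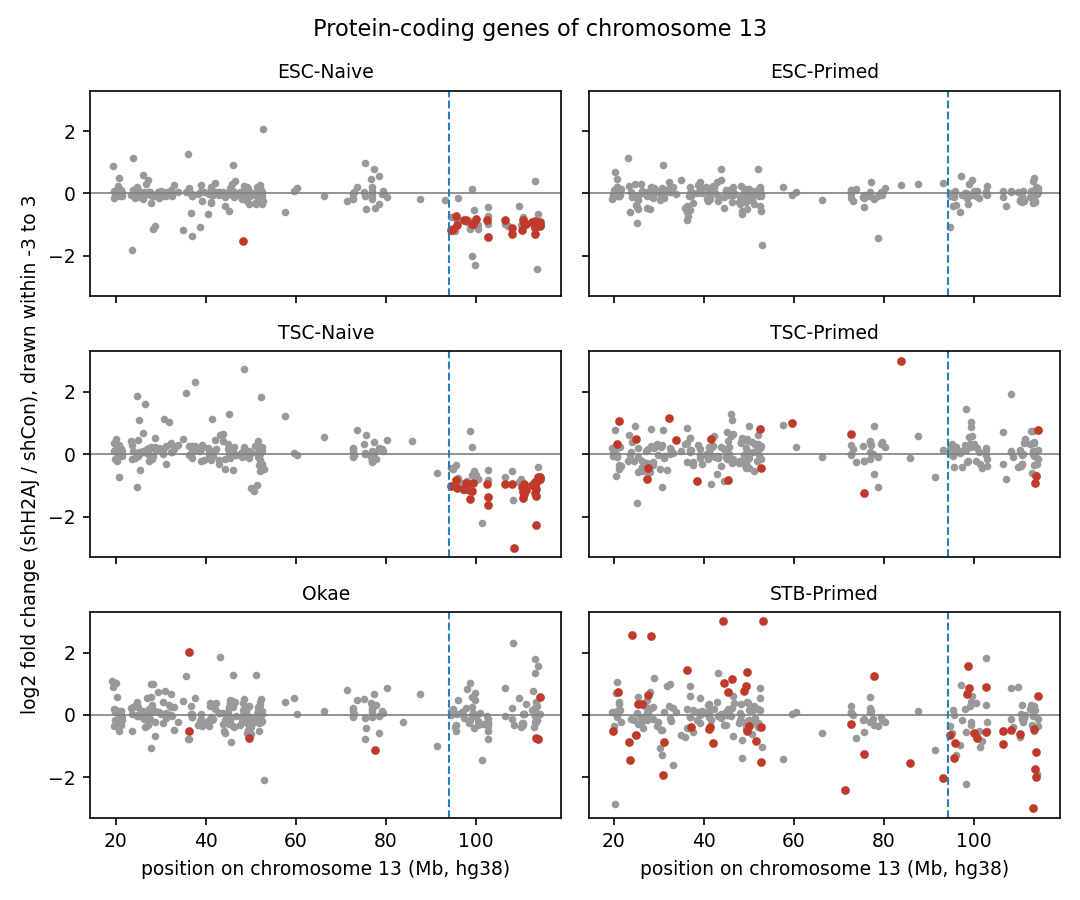
Log2 fold change (shH2AJ over shCon) of each protein-coding gene along chromosome 13 in the 6 models, red for genes past adjusted p 0.05 and a dashed line at the start of GPC6-AS1 (94154193). Values past a fixed limit in either direction are drawn at that limit. In ESC-Naive and TSC-Naive the protein-coding genes beyond the line have medians of -0.95 and -0.94, and those before it 0.00 and 0.08.

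**Figure D4:**
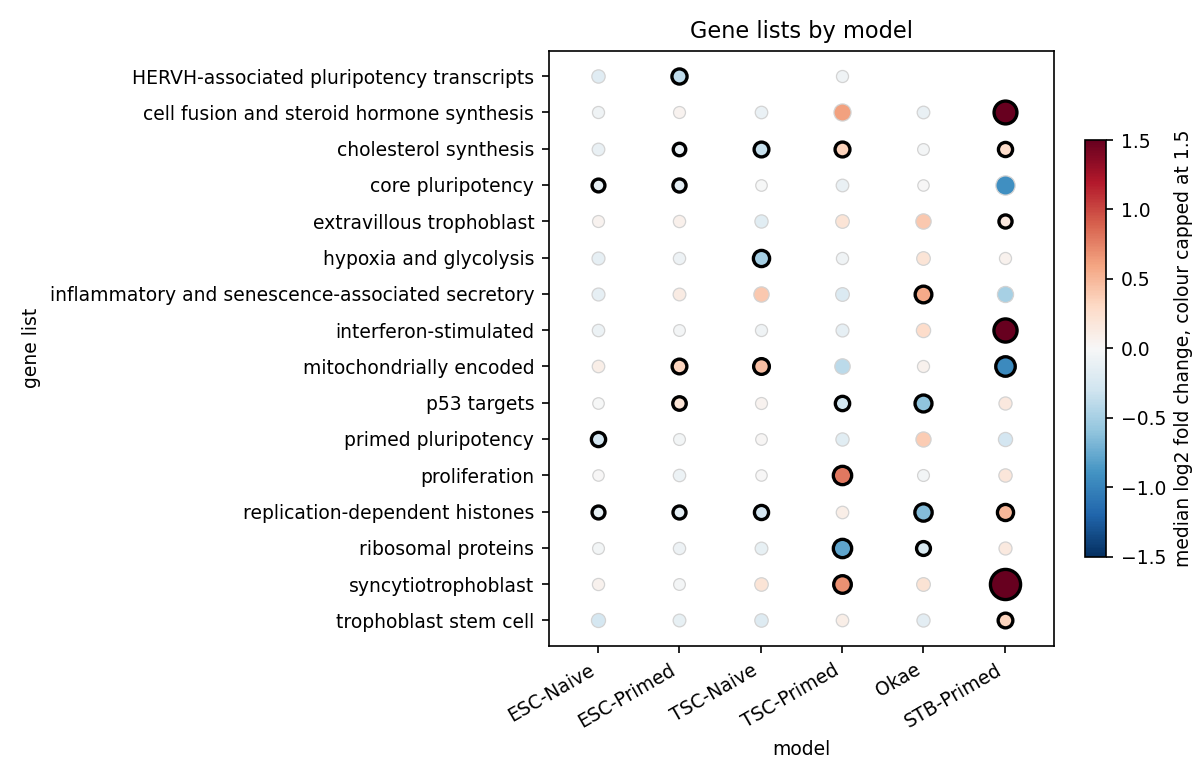
Median log2 fold change of the 16 lists past the threshold in at least 1 model, in the 6 models, with area by the size of the median and a black outline where camera gave an adjusted p below 0.05. The syncytiotrophoblast list in STB-Primed has the largest median, 3.28.

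The remaining 18 of 34 lists passed in no model, the lowest adjusted p being 0.052. Averaged over the 6 models, 854 genes rose and 825 fell among 13697 tested. ADAM32, of the ADAM family of membrane proteins (ENSG00000197140, chromosome 8, 39106990 to 39284911), rose by 1.99 (SE 0.16, adjusted p 2.8e-06), with the amino acid transporter SLC38A3 (1.37, SE 0.35), NLRP7 (1.21, SE 0.17), ECM1 (1.12, SE 0.24) and POU6F1 (1.05, SE 0.18). NLRP7 was at 0.24 CPM or lower in ESC-Primed and STB-Primed controls. In Okae, where it was high, it went down from 493.07 and 459.56 to 385.74 and 307.81. POU6F1 was at 0.33 CPM or lower in Okae and TSC-Naive controls. The sizes of these 2 averages are therefore poorly fixed. H2AJ (-1.81, SE 0.10), STX16-NPEPL1, a readthrough of 2 overlapping genes (-1.37, SE 0.21), and PCDHGB5 (-1.17, SE 0.20) fell. STX16-NPEPL1 was near the floor in Okae, at 0.66 and 0.7 CPM in controls and 0 and 0.1 in the shH2AJ libraries. The mitochondrial ribosomal RNAs MT-RNR1 (-1.16, SE 0.36) and MT-RNR2 (-1.11, SE 0.35) were called lower, with MT-RNR1 at 356.88 CPM in ESC-Primed control replicate 1 and 11.64 in replicate 2. Over the 3 trophoblast stem cell models 625 genes rose and 714 fell among 16360, with GABRR2 (2.12, SE 0.33), ADAM32 (2.02, SE 0.21) and SLC38A3 (1.84, SE 0.50) higher and H2AJ (-1.99, SE 0.14), STX16-NPEPL1 (-1.80, SE 0.31), CCDC144NL (-1.59, SE 0.39), TMEM169 (-1.46, SE 0.29) and OXCT1 (-1.28, SE 0.23) lower. The androgen receptor gene AR and FAM43A also passed, but had 0 counts in both TSC-Naive controls and log2 values of -0.12 and -0.25 without TSC-Naive. In TSC-Naive shH2AJ libraries CCDC144NL and TMEM169 were at 0.07 CPM or lower and GABRR2 at 0.29 or lower, near the floor. Without the naive models the totals were 2923 in place of 1679 and 2235 in place of 1339. The 30 named values recomputed so were those of both averages and of the trophoblast against embryonic stem cell difference below. Of these 14 held, 14 lost their call and 2 turned direction. Leaving out 1 library gave 1003 (TSC-Primed control replicate 2) to 2782 (Okae shH2AJ replicate 1) for the first average and 474 to 2673 for the second, with the same libraries at the ends.

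Calls were also compared between models. Of 5377 genes called in at least 1 model, 624 were called in the same direction in at least 2 models and 168 in opposite directions. TSC-Primed and Okae shared 63 genes higher and 82 lower, where independent lists would share 8.3 and 7.7, and 8 were opposite (16 if independent). TSC-Primed and STB-Primed shared 206 higher and 165 lower (57.3 and 59.4 if independent) with 68 opposite (117). The labels give these 2 models and ESC-Primed the same primed H1 source and do not describe separate infections. Overlap among them therefore does not tell a response to lower H2AJ from another change that the shH2AJ cells shared. Okae and STB-Primed shared 95 and 73 (30.4 and 22.4) with 62 opposite (52.2), so opposite calls too were above the number for independent lists. TSC-Naive and STB-Primed shared 10 higher and 20 lower (9.2 and 8.1) with 30 opposite (17.4), and TSC-Naive and TSC-Primed 3 and 5 (2.5 and 3) with 11 opposite (5.5) and a Pearson r of -0.06. Fold changes correlated across genes with Pearson r 0.31 for TSC-Primed and Okae and Spearman rho 0.32, where genes are not independent replicates. ESC-Naive and TSC-Naive, in neither of which H2AJ was detectably lowered, shared 25 genes lower (0.2 if independent), all 25 in distal chromosome 13, and 3 higher. Of ESC-Primed calls tested in both, 5 of 8 that rose and 5 of 5 that fell passed in the same direction in TSC-Primed. Those that fell include H2AJ, the targeted gene itself. With an absolute log2 fold change of at least 1 as well, 243 genes were shared by at least 2 models.

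The differences between models were tested directly. Knockdown effects in STB-Primed and TSC-Primed differed for 1521 of 19671 genes, 862 with a larger value in STB-Primed and 659 with a smaller one. Larger values belonged to OLAH, a thioesterase of fatty acid synthesis (4.42, SE 0.77), APOBEC2 (4.31, SE 0.62), ISM2 (3.95, SE 0.77), PCP4L1 (3.94, SE 0.35) and the sodium channel SCN2A (3.76, SE 0.96), and smaller ones to COL13A1 (-4.79, SE 0.76), SLC39A4 (-4.50, SE 0.32), SCG2 (-3.76, SE 0.47), GNA14 (-3.64, SE 0.51) and the opioid receptor OPRD1 (-3.42, SE 0.45). OLAH was at 0.04 and 0.42 CPM in STB-Primed controls. COL13A1 went from 0.4 and 0.58 to 0.06 and 0.07 in STB-Primed, so the sizes of both differences are poorly fixed. The syncytiotrophoblast list differed by a median of 1.76 (camera adjusted p 7.7e-10, adjusted p = 0.84 with an estimated correlation) and ribosomal proteins by 0.89 (2.2e-13, adjusted p = 0.84 with an estimated correlation). TSC-Primed and ESC-Primed differed for 98 of 16896 genes, led by SLC39A4 (4.06, SE 0.33), PADI1 (3.77, SE 0.38), NEK10 (2.76, SE 0.50), the carbonic anhydrase CA12 (2.55, SE 0.40) and the aggrecan protease ADAMTS4 (2.48, SE 0.40), against CXCL12 (-2.79, SE 0.30), RHBDL1 (-2.72, SE 0.47), LRRC4B (-2.64, SE 0.41), PMEPA1 (-1.54, SE 0.25) and LMNTD2 (-1.53, SE 0.31). Proliferation genes differed by a median of 0.78 (camera adjusted p 2.8e-27, adjusted p = 0.024 with an estimated correlation). Every 1 of the 8 libraries moved either count by more than 1.5 times when left out, to 383 (TSC-Primed shH2AJ replicate 2) to 2551 (STB-Primed control replicate 2) for the first and 6 (TSC-Primed control replicate 2 or ESC-Primed shH2AJ replicate 1) to 41 (TSC-Primed control replicate 1) for the second. With the compared groups fitted alone the counts were 3290 and 5899, by voomLmFit 3820 and 5240, and by the DESeq2 Wald test 2667 and 597.

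TSC-Naive and TSC-Primed differed for 497 of 17069 genes, among them GABRR2 (-6.15, SE 0.81), HLA-G (-4.90, SE 0.26), SLC39A4 (-4.57, SE 0.31), PADI1 (-4.25, SE 0.42) and PSG1 (-4.02, SE 0.71). The size for GABRR2 is poorly fixed, since it went from 0.37 and 0.79 to 0.07 and 0.29 CPM in TSC-Naive. Values higher in TSC-Naive belonged to AR, NCKAP5 and FAM43A, all at 0 counts in both TSC-Naive controls, and to the transcription inhibitor ID4 and the peptidase CPQ, which were at 0 counts in 1 of them. TSC-Naive and ESC-Naive differed for 8 of 15310 genes, with larger values in TSC-Naive for ID4, TMEM184A (2.89, SE 0.48), WDR72 (2.61, SE 0.34) and BMP7 (2.03, SE 0.23) and a smaller one for the metalloprotease MMP11 (-2.19, SE 0.35). TMEM184A went from 0.75 and 0.77 to 0.06 and 0.07 CPM in ESC-Naive, so its size is poorly fixed here and in the next difference. The 4 trophoblast models and the 2 embryonic stem cell models differed for 79 of 13697 genes, with CA12 (1.93, SE 0.32), SCG3 (1.84, SE 0.30), TMEM184A (1.66, SE 0.27), FLT1 (1.55, SE 0.31) and ATP6V1C2 (1.5, SE 0.32) above and the prostaglandin enzyme PTGS2 (-2.67, SE 0.41), SUGCT (-1.45, SE 0.24), SCG5 (-1.36, SE 0.23), KCNS1 (-1.30, SE 0.26) and AK9 (-1.15, SE 0.24) below. With 1 library left out these counts ran from 121 (TSC-Primed control replicate 2) to 1693 (TSC-Naive shH2AJ replicate 2), from 9 (ESC-Naive shH2AJ replicate 2) to 179 (TSC-Naive shH2AJ replicate 2) and from 14 (ESC-Primed control replicate 1 or either ESC-Primed shH2AJ library) to 543 (Okae shH2AJ replicate 1). For the first 2 differences, TSC-Naive against TSC-Primed and against ESC-Naive, the compared groups fitted alone by edgeR gave 28 and 0 (367 unadjusted for the latter), voomLmFit 106 and 0 (202 unadjusted) and the DESeq2 Wald test 1354 and 202. The joint fit called 190 and 489 genes for them in simulated data without any difference. Those libraries were drawn independently, whereas the real TSC-Naive libraries were more alike by replicate number, so these are not measured rates of false calls.

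The control libraries show how the models differ without knockdown, although the share of even numbers among counts up to 100 differed between models for a reason that was not tested. It was 64.1% to 67.4% in the naive models, 53.7% to 58% in Okae and STB-Primed, and 48.9% to 50.8% in ESC-Primed and TSC-Primed. ESC-Naive controls exceeded ESC-Primed controls in 12 of 13 naive pluripotency genes (median 7.02), such as NLRP7 (13.54, SE 0.46), SUSD2 (8.61, SE 0.49) and KLF5 (7.91, SE 0.34), and were lower in 13 of 14 primed genes (median -4.13), such as SOX11 (-9, SE 0.46), ZIC2 (-8.48, SE 0.66) and SFRP2 (-7.41, SE 1.33). H2AJ (-2.91, SE 0.25, adjusted p 3.8e-08), MACROH2A1 (-3.32, SE 0.26), H2AZ1 (-1.71, SE 0.17) and H2AC25 (-4.62, SE 0.23) were lower in ESC-Naive controls. So were 48 of 50 replication-dependent histones (median -2.91), while all 13 mitochondrially encoded genes were higher (median 3.41). The signal recognition particle RNA RN7SL2 took 0.174% and 0.142% of counts in ESC-Naive controls and 6.372% and 6.865% in ESC-Primed ones. In comparisons of naive with primed models, a trait of the cell state therefore cannot be told from a difference between the libraries. TSC-Naive controls, against ESC-Naive, were lower in all 11 naive genes (median -3.57). ALPG was at -9.15 (SE 0.49) and DPPA3 at -6.97 (SE 0.87). They were higher in 19 of 24 trophoblast stem cell genes (median 3.74). ENPEP was at 8.54 (SE 0.30), GATA2 at 6.85 (SE 0.56) and GATA3 at 6.75 (SE 0.56). MACROH2A1 was higher (3.96, SE 0.27), and H2AJ was not shown to differ (0.39, SE 0.24, adjusted p 0.18). Other lists were higher too: inflammatory genes (11 of 13, median 3.3), fibroblast and stromal genes (6 of 8, median 3.31), amnion genes (6 of 8, median 2.81) and extravillous genes (11 of 15, 2 lower, median 2.4). These comparisons called 10241 and 8355 genes.

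TSC-Primed controls, against ESC-Primed, were lower in all 9 core pluripotency genes measured (median -3.26), with POU5F1, the OCT4 gene, at -10.81 (SE 0.25) and TDGF1 at -6.75 (SE 0.22), and in all 17 primed genes (median -2.62). VRTN was at -9.38 (SE 0.24). They were higher in 15 of 18 trophoblast stem cell genes (median 2.75). TACSTD2 was at 8.48 (SE 0.67). Extravillous genes (14 of 17, 1 lower, median 2.59), inflammatory genes (12 of 15, 1 lower, median 2.42) and fibroblast and stromal genes (5 of 11, median 1.26) were higher as well. They were lower in H2AX (-2.60, SE 0.19), H2AZ1 (-2.85, SE 0.18) and H2AZ2 (-2.26, SE 0.15), while H2AJ was not shown to differ (-0.27, SE 0.23, adjusted p 0.3). All 31 proliferation genes (median -2.89) and all 50 replication-dependent histones (median -4.12) were lower in TSC-Primed controls too. STB-Primed controls, against TSC-Primed, were higher in 21 of 39 syncytiotrophoblast genes and lower in 2 (median 1.14), with the chorionic gonadotropin subunit CGA at 7.70 (SE 1.05), INHA at 6.61 (SE 0.36) and TFPI2 at 5.88 (SE 0.16), and in 12 of 20 extravillous genes (median 2.14; 2 lower). Lists of other cell types were higher as well: 7 of 13 fibroblast and stromal genes (none lower, median 2.62), 6 of 11 amnion genes (none lower, median 2.62) and 6 of 16 genes of epithelial-mesenchymal transition (1 lower, median 1.94). Of the extravillous genes MMP9 was at 5.88 (SE 0.46), PAPPA2 at 5.59 (SE 0.74) and HTRA4 at 5.19 (SE 0.58). STB-Primed controls were lower in LIN28A (-5.10, SE 0.41), SALL4 (-2.68, SE 0.14) and the stem cell factor TP63 (-1.74, SE 0.39), and higher in H2AJ (1.07, SE 0.23, adjusted p 0.0012). The trophoblast stem cell list went both ways, with 7 of 25 members higher and 8 lower (median -0.43). Of 31 proliferation genes 24 were lower and 0 higher (median -0.97). TSC-Naive controls, against TSC-Primed, were higher in NLRP7 (6.12, SE 0.34), PEG10 (3.33, SE 0.24), TEAD4 (3.06, SE 0.18) and LVRN (4.80, SE 0.35), and lower in KISS1 (-5.43, SE 0.73), SOX11 (-5.63, SE 0.38), H2AC25 (-3.75, SE 0.22) and H2AJ (-2.25, SE 0.24, adjusted p 6.5e-07). All 31 proliferation genes were higher (median 2.52). These comparisons called 11162, 8401 and 10103 genes.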

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

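The tests of chromosome 13, of reads shared between paralogs and of the protocadherin set were chosen after the results they concern had been seen. The tests of a few abundant genes, of a larger share of syncytiotrophoblast, of a chromosome 5 loss and of regrouped libraries were fixed before theirs were seen.

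In both naive models the protein-coding genes of chromosome 13 from 94154193 to 114337626 were lower in libraries labelled shH2AJ, with medians of -0.95 in ESC-Naive and -0.94 in TSC-Naive. A response to lower H2AJ is argued against for a shift of this size, because the lowest median of the same genes among the 4 models in which H2AJ fell was -0.24. That was in STB-Primed, where 15 of 69 were called lower and 5 higher (Fisher's exact test for the lower calls, two-sided, p 0.0014). A smaller shift in STB-Primed therefore stays open. Scaling or depth is argued against because the rest of chromosome 13 stood at 0.00 and 0.08 in the naive models. Loss of 1 copy of the region would give a value near -1, and every library labelled shH2AJ lay between -0.86 and -0.98. The boundary gene GPC6-AS1 (chromosome 13, 94154193 to 94187991) had 2 and 0 counts in ESC-Naive controls and 94 and 127 in libraries labelled shH2AJ, and 0 and 0 against 116 and 71 in TSC-Naive. The candidate explanation that fits these values is a chromosome 13 break with loss of 1 distal copy (-0.94) in the cells that gave both naive shH2AJ models, which no DNA data here can test.

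Syncytiotrophoblast genes were higher in the shH2AJ libraries of STB-Primed (median 3.28). Reads shared between paralogs are argued against by the 25 members outside multigene families, whose median was 2.4 with 18 called higher. A few genes taking most counts is argued against by a median of 3.27 over 48 members, 40 of them called higher, after the 17 most abundant genes were left out. A larger share of syncytiotrophoblast with no change within cells stays open: the median of the 21 members that mark STB-Primed over TSC-Primed controls minus that of the other 28 was -0.92, but this decides nothing, because the division used the control libraries of the fold itself and 10 of the 28 had no value in that comparison, and lists of other cell types went both ways: fibroblast and stromal -0.66 (camera adjusted p 0.2), stem cell 0.33 (0.0016, 0.80 with an estimated correlation) and extravillous 0.16 (0.022, 0.33 with an estimated correlation), with the syncytiotrophoblast member TFPI2 at -1.08. A change of expression within syncytiotrophoblast, a faster or fuller differentiation, and loss of H2A.J as such cannot be told apart in RNA from whole cultures.

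Clustered protocadherins (chromosome 5, 140786136 to 141512981) were lower in the shH2AJ libraries of STB-Primed, all 53 below 0 with a median of -1.58. Shared 3' exons of the alpha and gamma clusters are argued against as the whole cause by the single-exon beta genes, whose median was also -1.58 over 15 members. Loss of 1 copy of the region is argued against by its neighbours within 2 Mb on either side, at a median of 0.07 over 48 genes. Medians in the other models were -0.30 in ESC-Naive, -0.40 in ESC-Primed, 0.03 in TSC-Naive, -0.34 in TSC-Primed and -0.29 in Okae. The beta genes alone stood lower in ESC-Primed (median -0.75, 14 of 14 below 0, 1 called) and TSC-Primed (-0.67, 14 of 15 below 0, 1 called). Their medians were 0.01 in ESC-Naive and 1.6 in TSC-Naive, over 5 genes in each. A lower share of a cell type that expresses protocadherins was not tested, so the pattern may or may not lie within cells.

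Differences of the knockdown effect between models were picked out because each passed a test of the difference itself. In simulated data with no difference the test called 489 genes for TSC-Naive against ESC-Naive, more than the 8 seen, and 190 for TSC-Naive against TSC-Primed, where 497 were seen, against 0 for the other 3 differences, of which trophoblast against embryonic stem cell models also holds TSC-Naive. The simulation left out the likeness of TSC-Naive libraries by replicate number, so its counts need not hold for the real ones. STB-Primed and TSC-Primed differed for 1521 genes, with SLC39A4 at -4.50 (adjusted p 1.8e-06). Without control replicates 1 and 2 and shH2AJ replicates 1 and 2 in turn the count was 664, 2551, 566 and 819 for STB-Primed libraries and 608, 441, 503 and 383 for those of TSC-Primed. TSC-Primed and ESC-Primed differed for 98 genes, with SLC39A4 at 4.06 (adjusted p 2.1e-05), and in the same order 41, 6, 31 and 25 for TSC-Primed libraries left out and 30, 35, 6 and 10 for ESC-Primed. TSC-Naive and ESC-Naive differed for 8 genes, with BMP7 at 2.03 (adjusted p 0.0013, but 1 with these models fitted alone and with voomLmFit), and 96, 28, 67 and 179 for TSC-Naive libraries left out and 16, 37, 11 and 9 for ESC-Naive. TSC-Naive and TSC-Primed differed for 497 genes, with HLA-G at -4.90 (adjusted p 4.8e-08) and H2AJ itself at 2.97 (adjusted p 3.1e-04), and 1025, 478, 501 and 1693 for TSC-Naive libraries left out and 191, 121, 151 and 129 for TSC-Primed. Trophoblast and embryonic stem cell models differed for 79 genes, with PTGS2 at -2.67 (adjusted p 0.0083, but 0.27 without the naive models and 0.051 with voomLmFit). Its counts with libraries left out, in the same order, were 39, 60, 54 and 42 (ESC-Naive), 14, 17, 14 and 14 (ESC-Primed), 93, 134, 299 and 127 (TSC-Naive), 31, 23, 24 and 24 (TSC-Primed), 22, 23, 543 and 75 (Okae) and 105, 79, 42 and 29 (STB-Primed). Among gene lists whose medians had opposite signs, p53 targets differed by -0.45 between TSC-Primed and ESC-Primed (camera adjusted p 4.1e-04, 0.84 with an estimated correlation). Cholesterol synthesis differed by 0.50 between the same models (3.0e-08, 0.84 with an estimated correlation) and by -0.53 between TSC-Naive and TSC-Primed (2.3e-09, 0.84 with an estimated correlation). These list differences were not recomputed with libraries left out.

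Regrouping the libraries within their models tested whether chance gives as many genes. For the average over 6 models, 3 of 50 groupings, the real one included, gave at least the real 1679 genes, and the highest other gave 2320. For the average over 3 trophoblast stem cell models it was 3 of 50, with 1339 for the real grouping and 2485 for the highest other. For the difference between trophoblast and embryonic stem cell models it was 5 of 50, with 79 and 1164. This test does not exclude chance for these counts, but it is no clean test of chance either. All of the other groupings that reached the real count had set TSC-Naive libraries of the same replicate number together. For both averages those groupings also kept or mirrored TSC-Primed and so held its real contrast. In the average over 6 models they did the same for STB-Primed. For the difference, 3 of 4 kept or mirrored TSC-Primed and 3 of 4 STB-Primed, and the grouping with 1164 genes kept both. The high counts therefore cannot be credited to replicate numbers in TSC-Naive alone. With the replicate number as a block the counts were 2859, 2562 and 339.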

How the results depend on the processing

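The weighted fit (voomLmFit), unlisted genes taken as zeros, camera on the edgeR statistics, and leaving out distal chromosome 13 or the naive models were chosen after the results had been seen. H2AJ stayed below 0 in ESC-Primed, TSC-Primed, Okae and STB-Primed under all alternatives, and past the threshold except in ESC-Primed without either shH2AJ library. Of the named gene values, 336 of 343 kept direction and side of the threshold with DESeq2 size factors, 325 with the DESeq2 Wald test, 343 with no filter on low counts, 329 with the replicate block, 247 of 323 in fits to the compared groups alone, 264 of 343 with voomLmFit, 319 with unlisted genes as zeros, and 1597 of 1992 over all left-out libraries, where 384 lost their call and 11 gained one. Leaving out the naive models touched 30 named values, those of both averages and of the trophoblast against embryonic stem cell difference. Of these 14 held, 14 lost their call and 2 turned direction. The cause was not tested except where stated. Low levels were limited by the omission of genes whose highest count in a model was below 21.

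With the DESeq2 Wald test the counts were 141 in ESC-Naive, 92 in ESC-Primed, 611 in TSC-Naive, 2447 in TSC-Primed, 1545 in Okae, 2740 averaged over 6 models and 2572 over 3. For the differences it gave 2667 (STB-Primed against TSC-Primed), 597 (TSC-Primed against ESC-Primed), 202 (TSC-Naive against ESC-Naive), 1354 (TSC-Naive against TSC-Primed) and 637 (trophoblast against ESC). With an absolute log2 fold change of at least 1, a stricter rule, they were 463 in TSC-Primed, 271 in Okae, 2137 in STB-Primed, 19 and 113 for the averages and 243 for the overlap. Compared groups fitted alone by edgeR gave 14 in ESC-Naive, 4375 in ESC-Primed, 0 in TSC-Naive (301 unadjusted), 8966 in TSC-Primed, 387 over 3 models, 3290, 5899, 0 (TSC-Naive against ESC-Naive, 367 unadjusted) and 28 for the first 4 differences and 5367 for TSC-Naive against ESC-Naive controls. Calls shared with the joint fit in the same direction numbered 13, 14, 0, 1241, 250 in Okae and 2941 in STB-Primed. The replicate number as a block gave 532 in TSC-Naive, 2107 in TSC-Primed, 1323 in Okae, 2859 and 2562 for the averages, 2795, 228, 98, 1384 and 339 for the differences in the same order, and 48 list calls. In TSC-Naive libraries of the same number correlated across groups (r 0.971 and 0.972) more than the libraries of a group did (0.933 and 0.932), a hint from the data and not the design. ESC-Naive had the same order by less (0.978 and 0.978 against 0.971 and 0.974). There the block gave 58 calls, 38 of them among the 60 of the joint fit, and 7 of 11 named genes besides H2AJ passed. voomLmFit gave 38 in ESC-Naive, 3220 in ESC-Primed, 0 in TSC-Naive (280 unadjusted), 9072 in TSC-Primed, 957 in Okae, 334 over 3 models, and 3820, 5240, 0 (202 unadjusted) and 106 for the first 4 differences. Without distal chromosome 13, which held 30 of 60 calls in ESC-Naive and 38 of 179 in TSC-Naive, 12 and 112 genes passed, since its small p values no longer entered the adjustment. Without the naive models the averages gave 2923 and 2235, where AR stood at -0.12 and FAM43A at -0.25, below 0. Unlisted genes taken as zeros gave 8 in ESC-Primed, 1075 and 871 for the averages, 63, 4, 320 and 30 for the last 4 differences, and 15630, 13173, 18120 and 16265 for the control comparisons of ESC-Naive with ESC-Primed, TSC-Naive with ESC-Naive, TSC-Primed with ESC-Primed and TSC-Naive with TSC-Primed, more genes being tested.

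With 1 library left out, which leaves fewer samples, counts ran from 43 to 70 in ESC-Naive, 0 to 4 in ESC-Primed (edgeR, 0 without shH2AJ replicate 2, where 359 passed unadjusted), 158 to 963 in TSC-Naive, 173 to 406 in TSC-Primed, 82 to 1655 in Okae and 1897 to 3639 in STB-Primed. They ran from 1003 to 2782 and 474 to 2673 for the averages, and 383 to 2551, 6 to 41, 9 to 179, 121 to 1693 and 14 to 543 for the differences. The highest Okae count and the highest values of both averages and of the last difference came without Okae shH2AJ replicate 1, and the highest with TSC-Naive without its shH2AJ replicate 2. Control comparisons ran from 8987 to 9396, 7263 to 7846, 9495 to 9780, 6183 to 7397 (STB-Primed against TSC-Primed) and 8585 to 9829. H2AJ ran from -0.42 to -0.13 in ESC-Naive, -2.31 to -2.20 in ESC-Primed, -0.11 to 0.44 in TSC-Naive, -2.93 to -2.72 in TSC-Primed, -3.51 to -3.08 in Okae and -2.67 to -1.86 in STB-Primed.

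Of the 30 list calls, 29 held with camera on the edgeR statistics, 29 with the block, 12 with fry and 0 with an estimated correlation in camera, which widens the test where members move together. List calls ran from 27 to 43 with 1 library left out, and 96 of 120 single values held. The histone list in ESC-Naive turned direction without control replicate 2 or shH2AJ replicate 1 (adjusted p 0.72 in both, from 4.6e-06 without control replicate 1 over the left-out libraries), and mitochondrially encoded genes in TSC-Naive turned without shH2AJ replicate 1 (adjusted p 0.0064, in a range from 2.3e-13 without shH2AJ replicate 2 to 0.33 without control replicate 1).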

Other observations

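The zinc finger genes, the genes called in 4 or more models and the regions named here were picked out after their values had been seen, and no explanation is offered for them.

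ADAM32 rose in 4 models, by 3.30 (SE 0.47) in ESC-Primed, 2.96 (SE 0.36) in TSC-Primed, 2.73 (SE 0.35) in Okae and 1.91 (SE 0.34) in STB-Primed. The antisense transcript ENSG00000255026, on chromosome 11 from 287305 to 288987, rose in the same 4 models by 3.24 (SE 0.37), 6.92 (SE 0.47), 3.18 (SE 0.37) and 5.01 (SE 0.48). PCMTD2, on chromosome 20, fell in these models too, at -0.67 (SE 0.11), -0.43 (SE 0.12), -0.79 (SE 0.11) and -0.53 (SE 0.11). Its ESC-Primed call was lost without any 1 of the 4 libraries (adjusted p 0.59 and 0.36 without control replicates 1 and 2, and 0.55 and 0.7 without shH2AJ replicates 1 and 2). The values of the other genes of this paragraph in single models were not recomputed with libraries left out. TMCO3 was lower in 5 models and GAS6 in 4, both in distal chromosome 13. In the models in which H2AJ fell, TMCO3 fell in TSC-Primed (-0.94, SE 0.14), Okae (-0.75, SE 0.14) and STB-Primed (-1.74, SE 0.15), and GAS6, a ligand of TAM receptor kinases, fell in the same models (-0.71, SE 0.14; -0.77, SE 0.14; -1.18, SE 0.14). In all, 75 genes were called in the same direction in at least 3 models, 30 higher and 45 lower.

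HLA-G moved in opposite directions between models. It rose in TSC-Primed from 18.64 and 19.83 to 65.49 and 60.99 CPM and in STB-Primed from 2.68 and 2.35 to 23.4 and 23.56, rose in Okae from 62.11 and 53.03 to 97.26 and 88.72 (0.69, adjusted p 0.016, not recomputed with libraries left out), and was lower in TSC-Naive libraries labelled shH2AJ (-3.18, adjusted p 2.3e-06, but 1 with that model fitted alone and with voomLmFit). Of 473 protein-coding zinc finger (ZNF) genes in STB-Primed, 89 fell and 28 rose, with a median of -0.26 (Fisher's exact test for the lower calls, p 1.1e-10, where genes are not independent replicates). In TSC-Primed 9 of 475 fell and 17 rose, with a median of -0.05.

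The signal recognition particle RNA RN7SL2, which ribosomal depletion leaves behind, took 3.98% and 8.91% of counts in STB-Primed controls and 8.52% and 9.46% in the shH2AJ libraries, and 3.58% and 1.3% in the Okae shH2AJ libraries. In every library of the naive models it took 0.433% or less. The replicates of each of the 12 groups differed by more than counting error, with a chi-square per degree of freedom from 3.98 in the TSC-Primed shH2AJ libraries to 169.31 in those of Okae.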
